A study of Homo sapiens with 9 samples.

How the data were processed

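RNA was measured in 9 libraries of U87MG, an established human glioblastoma cell line, in 3 groups of 3 samples: the parent line (parent), a line kept continuously in 50 µM temozolomide (R50), and a line taken off the drug after 2 months of treatment (R50_OFF). Temozolomide (TMZ) is a DNA-alkylating drug used against glioblastoma. The group and replicate number of each sample came from the sample titles. Per the labels' protocols, poly-A RNA was made into strand-specific libraries and read as single ends of 50 bases. The submitters' processing notes name bcl2fastq 2.17.1.14 and the build hg38. The aligner, the counting tool, its strand setting and the annotation version are not given in the sources used here. Glioma stem-like cells that the series text also mentions were not analysed here.

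The authors deposited a table of 33264 genes in 9 value columns, a linear signal that, per the file headers, had been normalized between libraries and divided by the median transcript length in kilobases. The values are not scaled to a fixed library total, and the normalization method is not named. Within each gene the values proved to be whole multiples of a step set by a library factor and a transcript length, for 100% of the genes within a relative tolerance of 2e-11. The library factors found this way differed from median-of-ratios factors by 0% at most. The traced reads summed to 28.8 M to 35.9 M per library, and 22904 to 24892 genes lay above 0. Division by transcript length multiplies a gene by the same number in every library, so it moves levels between genes but not fold changes, apart from the effect of the pseudocount. Of the gene IDs, 33137 (99.62%) matched GENCODE version 44 on hg38, which supplied coordinates, counted from 1. Symbols came from a separate reference list of gene names, which also matched 33137 IDs.

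Tests used limma 3.58.1 in R 4.3.3 on log2(value + 1), with an empirical Bayes trend and all 9 samples in 1 fit with 6 residual degrees of freedom. The 16456 genes with a value of at least 10 in at least 3 libraries were tested in 3 comparisons, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Every fold change is on the log2(value + 1) scale, which understates the change of genes with low values. Means and SDs are of the deposited values, and the SE belongs to the log2 change. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 35 lists of a comparison. The camera test was repeated with the correlation estimated from the data, and list members were also counted with p-values adjusted over the list alone. No list passed with an estimated correlation, where the lowest adjusted p of any list was 0.365.

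The comparisons, the lists and the rule for named genes were fixed before the data were examined. Per comparison the rule took the 10 largest rises and the 10 largest falls past the threshold among genes with a symbol. Such a gene needed a mean in its higher group at or above the median of tested genes and 3 libraries of each group that did not overlap. XIST and Y-linked genes were left out. The rule added up to 4 members with the largest change from each described list. It also named 17 genes whatever their result, 14 of which were tested, among them MSH6, PMS2, MPG, CDKN1A, MDM2, EGFR, ITGA5, SOX2, NES and ABCG2. Results of some genes that the rule named are not reported here. ABCB1 did not reach the minimum value, and MGMT and CDKN2A were not analysed here. Reads of near-identical copies may be split between them, so values of MAGE, CSAG1, HLA, AKR1C, zinc finger and keratin genes are uncertain. The same holds for antisense genes, because the strand setting of the counting is not given.

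The fit was tested on simulated data for R50 against parent with 15939 genes. It recovered 40.8% of genes changed by 1.25-fold, 77.1% at 1.5-fold, 79.6% at 2-fold and 93.8% at 4-fold, with 6 false calls among 15726 unchanged genes. The simulation gave every gene and library the same dispersion of 0.0024 and independent genes, so these rates may not hold for the real libraries. Replicates of a group differed by more than sampling noise in every pair, with a chi-square per gene of 2.42 to 18.98, and each was counted as 1 sample. R50 replicate 2 stood apart, at 15.81 with replicate 1 and 18.98 with replicate 3, beside 4.79 for R50 replicates 1 and 3. The resistant lines are described as clonal, and nothing says that the replicates came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical, and each resistant line stands for 1 clonal line.

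Chromosomes and windows of 10 megabases with at least 10 tested genes were compared with 10000 random gene sets of the same size, and intervals of their shifts came from 2000 bootstrap draws. The GC content came from the GENCODE transcripts. Alternatives were a pseudocount of 0.1 or 8, no filter, a minimum value of 50, quantile normalization, median-ratio rescaling, no trend, the 2 groups alone, the replicate number as a block and each sample left out in turn. A planned count test on recovered reads was not run, because the columns have no single step. A limma voom fit on the traced reads and a fit on reads not divided by length were added after the data were seen. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.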

Results

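Messenger RNA was measured in 9 libraries of U87MG, an established human glioblastoma cell line: 3 of the untreated parent line (parent), 3 of a line kept in temozolomide (R50) and 3 of a line from which the drug had been withdrawn (R50_OFF). The traced reads came to 28.8 M to 35.9 M per library, and 16456 genes were tested with limma and Benjamini-Hochberg adjustment. The groups stood apart from each other, with 57.4% of the variance on the first principal component, on which R50_OFF lay between parent and R50, and 24.8% on the second, on which R50_OFF stood apart from both. Values are deposited normalized signal as mean ± SD with n = 3 per group, and fold changes are on the log2(value + 1) scale, which understates the change of genes with low values. In every gene given below as risen or fallen, the 3 libraries of one group lay beyond the 3 of the other. The p-values measure only the spread between these samples, since each resistant line is 1 clonal line and nothing says that its replicates were separate cultures.

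The comparison of R50 with parent asked which genes differed under continuous culture in the drug. In R50, transcripts of inflammatory cytokines, DNA replication genes, growth factors and integrins were lower than in parent, while p53 target genes were higher, all list calls that were lost with an estimated correlation. IL1B, which encodes an inflammatory cytokine, fell from 17998 ± 1756 in parent to 242 ± 15.1 in R50. MSN, which encodes moesin, a linker between the cell membrane and the actin skeleton, fell from 57857 ± 611 to 401 ± 71.5. TENM2, which encodes a cell adhesion protein of neurons, rose from 16.6 ± 5.26 to 11989 ± 174, and CHL1, a neural adhesion protein of the L1 family, rose from 0.523 ± 0.906 to 591 ± 49.9.

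The falls were led by MSN (X:65588377 to 65741931), which changed by -7.18 (SE 0.11, adjusted p = 1.29e-11). SLFN11, which encodes a protein that blocks replication in cells with damaged DNA, fell from 1007 ± 49 to 7.25 ± 3.83, a change of -7.06 (SE 0.33, adjusted p = 1.53e-08). HGF, the ligand of the MET receptor, fell from 4826 ± 318 to 73.2 ± 4.62. LMO2, SYNDIG1, FAR2, PDZRN3, ACP3 and TBX2 made up the rest of the 10 largest falls, down to TBX2 at -5.62. The rises were led by TENM2 at 9.45 (SE 0.18, adjusted p = 3.62e-11) and CHL1. THY1, a surface glycoprotein, rose from 12.8 ± 9.73 to 3568 ± 401. The interleukin subunit gene EBI3 rose from 5.27 ± 4.65 to 1422 ± 257, and the protease inhibitor gene SLPI rose from 3.1 ± 2.88 to 692 ± 63.5. KRT81, a hair keratin with near-identical copies, was 2.45 ± 0.742 in parent and 864 ± 95.1 in R50. The other 4 of the 10 largest rises were ZNF468, ZNF91, ZNF681 and LINC01224, all on chromosome 19.

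Genes of S phase and DNA replication fell together. Of 21 tested, 18 were lower and 0 higher, also 18 and 0 adjusted over the list alone, with a median of -0.72 (camera adjusted p = 2.47e-06). The list did not pass with an estimated correlation, where adjusted p = 0.389 with an estimated correlation. MCM6, a subunit of the replicative helicase, fell from 13679 ± 8.87 to 4136 ± 210, RRM2, a subunit of ribonucleotide reductase, from 21848 ± 377 to 8117 ± 712, and the transcription factor gene E2F1 from 1690 ± 24.5 to 636 ± 11.8. Of 24 p53 targets, 16 were higher and 3 lower, also 16 and 3 adjusted over the list alone, with a median of 0.36 (camera adjusted p = 0.00715, adjusted p = 0.389 with an estimated correlation). CDKN1A, which encodes the cell cycle inhibitor p21, rose from 4566 ± 53.9 to 9089 ± 535, a change of 0.99. BTG2 rose from 76.5 ± 13.6 to 284 ± 18.4, GDF15 from 1340 ± 87.6 to 3097 ± 468, and MDM2, a ubiquitin ligase gene, by 0.34 (adjusted p = 0.00605). MCM6 and RRM2 lie on chromosome 2 and CDKN1A on chromosome 6, whose tested genes had median changes of -0.34 and 0.318. How much of these genes' changes goes with their chromosome was not tested.

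Of the 3 lists of DNA repair genes, 2 were lower as well. Of 15 genes of homologous recombination and the Fanconi anemia pathway, 13 were lower and 1 higher, also 13 and 1 adjusted over the list alone, with a median of -0.41 (camera adjusted p = 0.00279, adjusted p = 0.546 with an estimated correlation). BRCA1 fell from 2541 ± 96.3 to 1213 ± 102 and BRCA2 from 741 ± 44.9 to 383 ± 60.7. Of 8 mismatch repair genes, 6 were lower and 0 higher, also 6 and 0 adjusted over the list alone, with a median of -0.56 (camera adjusted p = 0.0403, adjusted p = 0.567 with an estimated correlation). The exonuclease gene EXO1 fell from 2691 ± 151 to 604 ± 50.6 and MSH6 by 0.93 on the log2 scale (adjusted p = 1.28e-07). MSH6 lies on chromosome 2, whose 1114 tested genes had a median change of -0.34. PMS2 fell by 0.40 (adjusted p = 0.0143, 0.00248 to 0.0635 over the alternatives), a call lost without parent replicate 3 (0.0635) and without R50 replicate 1 (0.0505). Of 12 genes of alkylation damage and base excision repair, 3 were higher and 5 lower, also 3 and 5 adjusted over the list alone, with a median of -0.08, and the list did not pass (camera adjusted p = 0.729). Its glycosylase gene MPG, at -0.12, did not pass the test (adjusted p = 0.0727). MGMT, whose product removes the alkyl lesion from guanine, and CDKN2A were not analysed here.

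Inflammatory and growth factor transcripts had the lowest medians of the called lists. Of 17 NF-kB cytokines and targets, 13 were lower and 4 higher, also 13 and 4 adjusted over the list alone, with a median of -2.37 (camera adjusted p = 0.00329, adjusted p = 0.567 with an estimated correlation). The chemokine gene CXCL8 fell from 2606 ± 456 to 145 ± 10.5 and the growth factor gene CSF3 from 2428 ± 600 to 138 ± 19.4. Of 23 growth factor receptors and ligands, 17 were lower and 4 higher, also 17 and 4 adjusted over the list alone, with a median of -0.83 (camera adjusted p = 0.000929, adjusted p = 0.389 with an estimated correlation). EREG, a ligand of the EGF receptor, fell from 10875 ± 142 to 1290 ± 206, and the receptor gene EGFR fell by 0.73 (adjusted p = 6.36e-07). CXCL8 and EREG lie on chromosome 4 and EGFR on chromosome 7, whose tested genes had smaller median falls, at -0.272 and -0.198.

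Adhesion and matrix genes moved in both directions but were mostly lower. Of 15 integrins, 10 were lower and 3 higher, also 10 and 3 adjusted over the list alone, with a median of -0.59 (camera adjusted p = 0.0328, adjusted p = 0.567 with an estimated correlation). ITGA5, the fibronectin receptor subunit, fell from 72459 ± 2975 to 28800 ± 2205, a change of -1.33 (adjusted p = 1.38e-08), and ITGA11 fell from 1777 ± 74.8 to 115 ± 7.92. Of 23 collagens and matrix proteins, 15 were lower and 7 higher, also 15 and 7 adjusted over the list alone, with a median of -0.67 (camera adjusted p = 0.0246, adjusted p = 0.567 with an estimated correlation). COL8A1 fell from 2657 ± 123 to 198 ± 22.3, whereas the elastin gene ELN rose from 2.26 ± 2.01 to 186 ± 21.9.

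Metabolic and stress genes were lower in 3 lists. Of 20 hypoxia response genes, 16 were lower and 3 higher, also 16 and 3 adjusted over the list alone, with a median of -0.70 (camera adjusted p = 0.00279, adjusted p = 0.567 with an estimated correlation). PFKFB4 fell from 8936 ± 610 to 2940 ± 38.6. Of 18 glycolysis genes, 15 were lower and 1 higher, also 15 and 1 adjusted over the list alone, with a median of -0.38 (camera adjusted p = 0.00279, adjusted p = 0.567 with an estimated correlation). HK2, which encodes a hexokinase, fell from 2466 ± 59.9 to 1139 ± 20.1. Of 13 reference genes, a list that shares GAPDH and PGK1 with glycolysis, 6 were lower and 0 higher, also 6 and 0 adjusted over the list alone, with a median of -0.19, and the list did not pass (camera adjusted p = 0.0678, 0.0103 to 0.574 over the alternatives). Of 17 NRF2 targets, genes of the oxidative stress response, 12 were lower and 3 higher, 13 and 3 adjusted over the list alone, with a median of -0.42 (camera adjusted p = 0.0139, adjusted p = 0.389 with an estimated correlation). HMOX1, which encodes heme oxygenase, fell from 25572 ± 3644 to 8370 ± 324.

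Among single genes fixed beforehand, SOX2, a transcription factor of neural stem cells, was listed at 0 in all parent libraries and was 39.5 ± 5.65 in R50 (adjusted p = 4.81e-08), a low level. The drug efflux pump gene ABCG2 fell from 63.2 ± 7.39 to 0.0735 ± 0.127. NES, the neural progenitor filament nestin, was 65.2 ± 4.94 in parent and 63.6 ± 2.64 in R50 (adjusted p = 0.858), and ABCB1 did not reach the minimum level.

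In all, 5206 genes were higher and 5216 lower in R50, 63.3% of those tested, of which 2062 and 1489 changed at least 2-fold. With quantile normalization 5 of the 11 called lists no longer passed: NRF2 targets (adjusted p = 0.0511, 0.000222 to 0.0511 over the alternatives), collagens (0.0511, 0.00169 to 0.0511), glycolysis, whose median shrank to -0.20 (0.124, 2.81e-05 to 0.124), integrins (0.0578, 0.00378 to 0.0918) and mismatch repair (0.052, 0.00264 to 0.0797). Without R50 replicate 1 integrins and mismatch repair stood at 0.0501 each, without R50 replicate 3 mismatch repair at 0.0759, and with the higher minimum value integrins at 0.0918 and mismatch repair at 0.0797. Without R50 replicate 2 the median of NRF2 targets was -0.64 (adjusted p = 0.019).

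**Figure D1:**
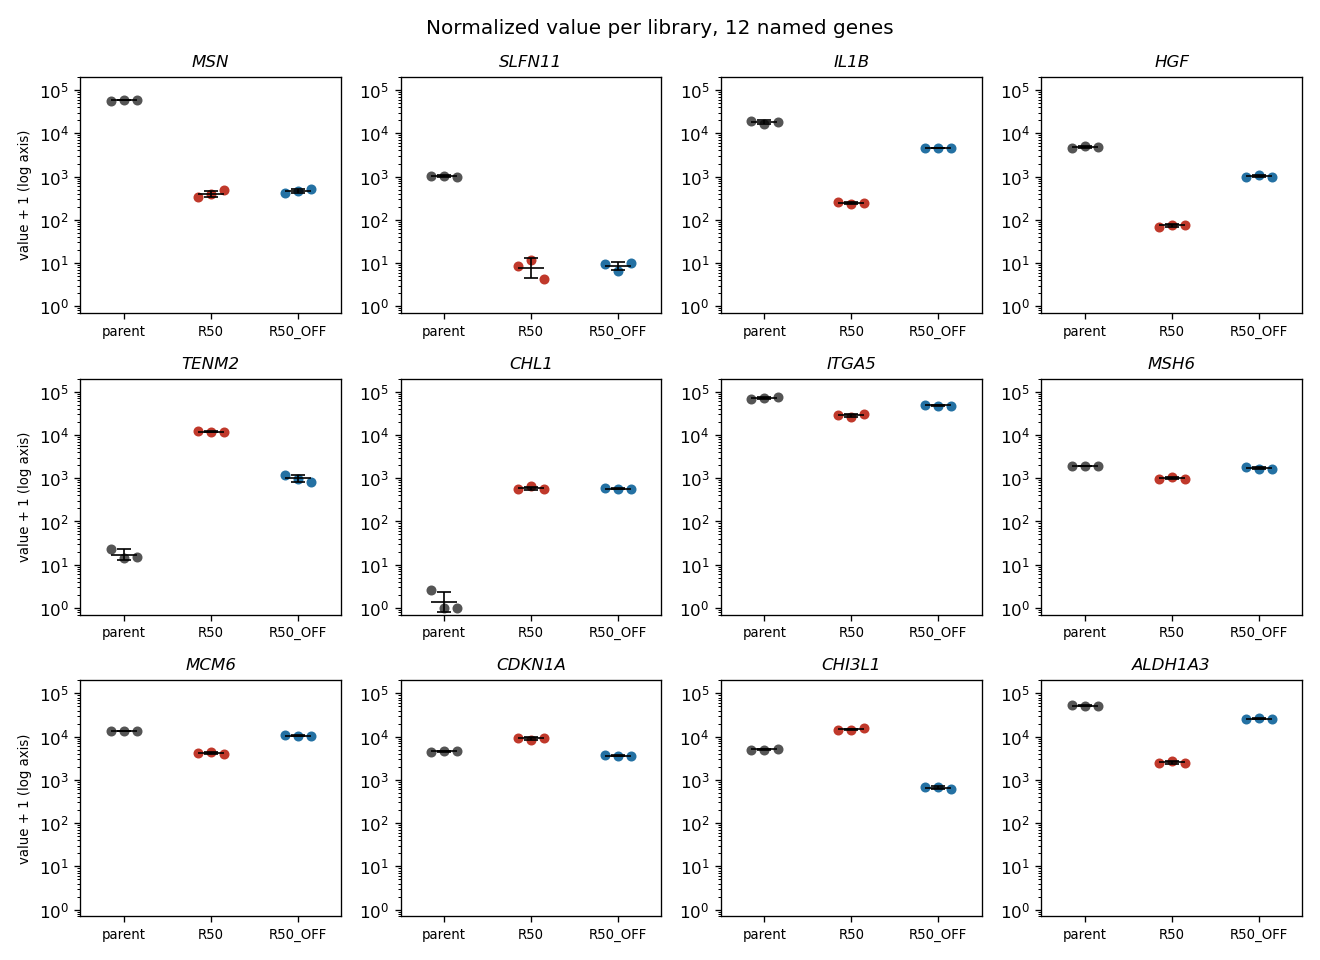
Values of 12 named genes in each library (points), with a bar for the mean and SD of log2(value + 1), on a log axis of value + 1 for parent, R50 and R50_OFF. MSN and SLFN11 were low in both resistant lines, whereas R50_OFF lay between parent and R50 for IL1B (4551 ± 95.1) and HGF (1011 ± 56.7).

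The comparison of R50_OFF with parent asked what differed in the line from which the drug had been withdrawn. R50_OFF had lower transcripts of antigen presentation, matrix, integrin and hypoxia genes than parent, and higher transcripts of oxidative phosphorylation and HOX genes, and all of these list calls were lost with an estimated correlation. MSN fell from 57857 ± 611 to 456 ± 48.1, a change of -6.99 (SE 0.11, adjusted p = 6.87e-11), and SLFN11 from 1007 ± 49 to 7.74 ± 1.78, a change of -6.87 (SE 0.33, adjusted p = 5.2e-08). CHL1 rose from 0.523 ± 0.906 to 577 ± 20.9, and ADARB2, a brain gene related to RNA-editing enzymes, was listed at 0 in all parent libraries and was 435 ± 20.4 in R50_OFF.

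Several of the largest rises were X-linked genes that are normally active in the germline. MAGEB2 rose from 11.5 ± 1.64 to 1672 ± 51.7, MAGEA12 from 8.27 ± 2.72 to 1396 ± 49.6 and its neighbour CSAG1 from 14.9 ± 3.89 to 2196 ± 14.3, values that are uncertain because these families hold near-identical copies. Of 9 germline and cancer-testis genes fixed beforehand, 5 were higher and 3 lower, also 5 and 3 adjusted over the list alone, with a median of 0.65, and the list did not pass (camera adjusted p = 0.183, 0.0218 to 0.214 over the alternatives). ITM2A, a membrane protein gene, rose from 0.447 ± 0.774 to 529 ± 28.5. RGS10, ARL10 and the pseudogene NCOR1P4 were also among the 10 largest rises, NCOR1P4 the last of them at 6.20. The other large falls were SYNDIG1, the water and glycerol channel gene AQP9 (1094 ± 18.8 to 23.8 ± 1.06), TBX2, ST8SIA5, MEST, LMO2, PAMR1 and CYRIA, the last at -3.85.

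Of 17 antigen presentation genes, 14 were lower and 0 higher, also 14 and 0 adjusted over the list alone, with a median of -0.49 (camera adjusted p = 0.000556, adjusted p = 0.461 with an estimated correlation). HLA-B, a class I molecule whose reads can be split with its copies, fell from 12929 ± 270 to 6966 ± 33.7. Of 23 collagens and matrix proteins, 14 were lower and 2 higher, 16 and 4 adjusted over the list alone, with a median of -0.68 (camera adjusted p = 0.000669, adjusted p = 0.443 with an estimated correlation). FN1, which encodes fibronectin, fell from 43670 ± 2633 to 6074 ± 276, whereas the thrombospondin gene THBS1 rose from 1338 ± 147 to 6568 ± 360. Of 15 integrins, 11 were lower and 2 higher, also 11 and 2 adjusted over the list alone, with a median of -0.78 (camera adjusted p = 0.002, adjusted p = 0.365 with an estimated correlation). ITGA5 fell by 0.59 (adjusted p = 1.47e-05), and ITGA6, the laminin receptor subunit, rose from 59.6 ± 2.21 to 732 ± 48.6. Of 15 matrix proteases and inhibitors, 8 were lower and 4 higher, also 8 and 4 adjusted over the list alone, with a median of -0.73 (camera adjusted p = 0.0472, adjusted p = 0.461 with an estimated correlation). The protease gene ADAMTS1 fell from 7557 ± 323 to 1958 ± 47.1.

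Of 21 nuclear genes of oxidative phosphorylation, 14 were higher and 0 lower, also 14 and 0 adjusted over the list alone, with a median of 0.25 (camera adjusted p = 0.002, adjusted p = 0.531 with an estimated correlation). NDUFS3, a subunit of complex I, rose from 3937 ± 40.1 to 6566 ± 358. Of 13 mitochondrially encoded genes, 10 were lower and 0 higher, also 10 and 0 adjusted over the list alone, with a median of -0.40 (camera adjusted p = 0.0139, adjusted p = 0.533 with an estimated correlation). MT-ND5 fell from 17415 ± 1523 to 11307 ± 351. Of 17 HOX genes, transcription factors of body patterning, 12 were higher and 1 lower, also 12 and 1 adjusted over the list alone, with a median of 0.39 (camera adjusted p = 0.00539, adjusted p = 0.365 with an estimated correlation). HOXC10 rose from 19.3 ± 6.7 to 223 ± 23.7, and HOXD10 was 28.1 ± 7.46 in parent and listed at 0 in all R50_OFF libraries.

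Of 20 hypoxia response genes, 15 were lower and 2 higher, also 15 and 2 adjusted over the list alone, with a median of -0.31 (camera adjusted p = 0.00169, adjusted p = 0.472 with an estimated correlation). EGLN3, an oxygen-sensing hydroxylase gene, fell from 2116 ± 348 to 222 ± 30.7. Of 23 growth factor receptors and ligands, 14 were lower and 2 higher, also 14 and 2 adjusted over the list alone, with a median of -0.40 (camera adjusted p = 0.00613, adjusted p = 0.365 with an estimated correlation). HGF fell to 1011 ± 56.7. Of 17 NRF2 targets, 11 were lower and 1 higher, also 11 and 1 adjusted over the list alone, with a median of -0.41 (camera adjusted p = 0.00645, adjusted p = 0.365 with an estimated correlation). HMOX1 fell to 6037 ± 20.6. Of 10 drug efflux transporters, 8 were lower and 1 higher, also 8 and 1 adjusted over the list alone, with a median of -0.39 (camera adjusted p = 0.0128, adjusted p = 0.365 with an estimated correlation). ABCG2 fell by 1.37 (adjusted p = 0.00152), and ABCC4 rose by 0.64 (adjusted p = 4.56e-05). Of 19 genes of cholesterol synthesis, 11 were lower and 4 higher, also 11 and 4 adjusted over the list alone, with a median of -0.28 (camera adjusted p = 0.0457, adjusted p = 0.461 with an estimated correlation). INSIG1, a regulator of sterol synthesis, fell from 3718 ± 113 to 1678 ± 75.3.

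Of 8 mismatch repair genes, 6 were lower and 0 higher, 7 and 0 adjusted over the list alone, with a median of -0.28 (camera adjusted p = 0.0278, adjusted p = 0.461 with an estimated correlation). EXO1 fell from 2691 ± 151 to 1639 ± 79.1. The falls of MSH6 by 0.16 (adjusted p = 0.0377, 0.0149 to 0.159 over the alternatives) and PMS2 by 0.36 (0.0298, 0.0129 to 0.12) were small. Each lost its call without parent replicate 1 (0.0953 and 0.055), parent replicate 3 (0.0814 and 0.12), R50_OFF replicate 2 (0.117 and 0.103) or R50_OFF replicate 3 (0.126 and 0.0522), and MSH6 also without parent replicate 2 (0.0925). MDM2 was at -0.18 (adjusted p = 0.119, 0.0156 to 0.322 over the alternatives) and EGFR at -0.08 (0.264), neither past the test, though MDM2 passed in 2 alternatives. MPG rose by 0.23 (adjusted p = 0.00365), CDKN1A fell by 0.34 (0.00018) and NES fell by 1.61 (5.69e-06). SOX2, listed at 0 in parent, was 24.7 ± 2.91 in R50_OFF.

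In all, 4334 genes were higher and 4231 lower in R50_OFF, 52% of those tested, of which 1238 and 841 changed at least 2-fold. The list of matrix proteases lost its call in 11 of 20 alternatives (0.00985 to 0.0899 over the alternatives), among them without parent replicate 3 (adjusted p = 0.0544), R50 replicates 1, 2 and 3 (0.0717, 0.0899 and 0.0592) and R50_OFF replicates 1 and 3 (0.0503 each). Cholesterol synthesis lost it in 8 (0.00781 to 0.0925), among them without R50 replicates 2 and 3 (0.0622 and 0.056) and R50_OFF replicates 1 and 3 (0.0574 and 0.0503), and mismatch repair lost it with quantile normalization (0.0578, 0.0046 to 0.0578).

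**Figure D2:**
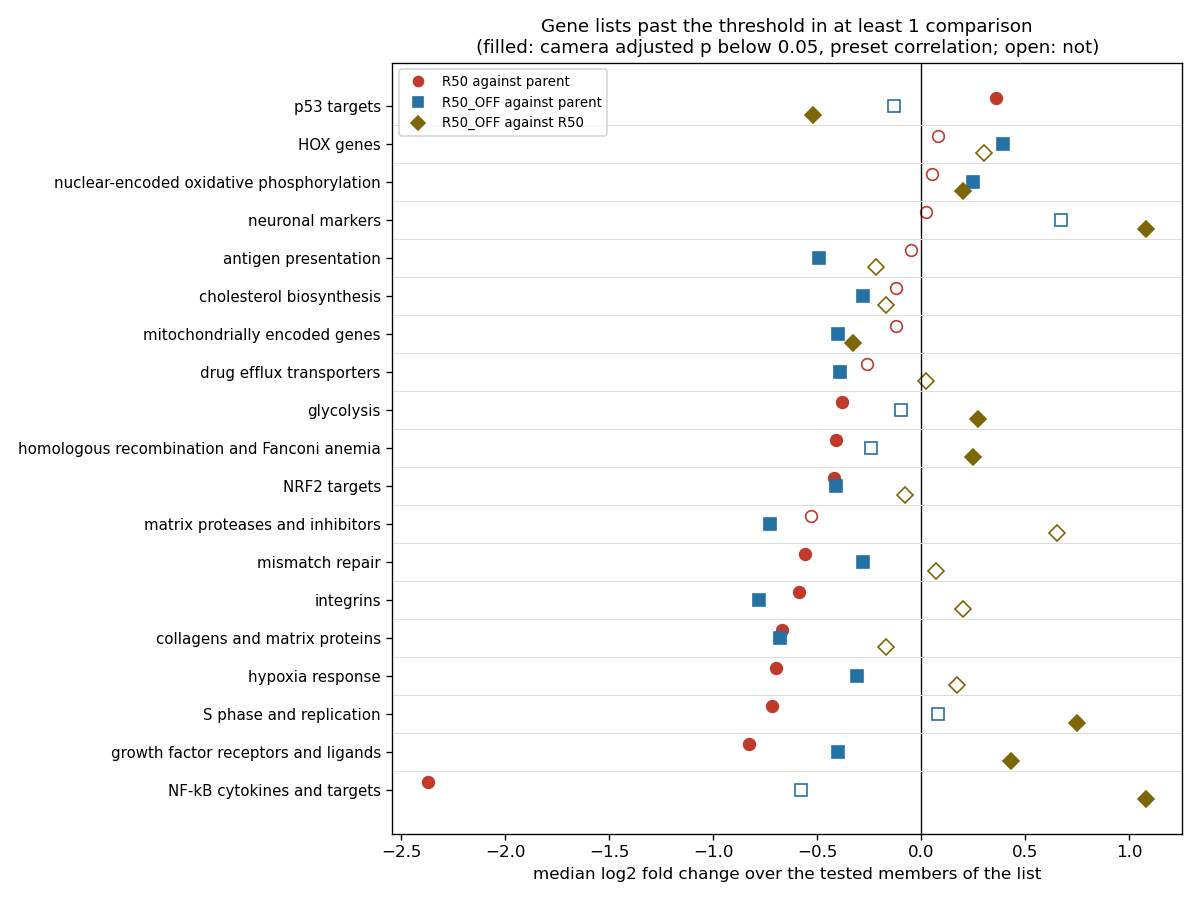
Median log2 fold change over the tested members of 19 gene lists, with 1 symbol per comparison, filled where camera with the preset correlation gave an adjusted p below 0.05. S phase genes were at -0.72 in R50 against parent and at 0.75 in R50_OFF against R50.

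The comparison of R50_OFF with R50 asked how the released line differed from the one still in the drug. Replication genes and NF-kB cytokines were higher in R50_OFF than in R50, and p53 targets were lower, although none of these lists passed with an estimated correlation. E2F1 rose from 636 ± 11.8 in R50 to 1940 ± 91.6 in R50_OFF, and IL1B rose from 242 ± 15.1 to 4551 ± 95.1. CDKN1A fell from 9089 ± 535 to 3611 ± 102. RARRES2, which encodes the adipokine chemerin, fell from 679 ± 36.5 to 0.42 ± 0.728, and APOE, a lipid carrier, fell from 1674 ± 104 to 22.9 ± 6.15.

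Of 21 genes of S phase and DNA replication, 18 were higher and 0 lower, 19 and 0 adjusted over the list alone, with a median of 0.75 (camera adjusted p = 7.95e-08, adjusted p = 0.372 with an estimated correlation). MCM6 rose from 4136 ± 210 to 10554 ± 324. Of 24 p53 targets, 20 were lower and 3 higher, also 20 and 3 adjusted over the list alone, with a median of -0.52 (camera adjusted p = 0.000384, adjusted p = 0.372 with an estimated correlation). FDXR fell from 1733 ± 144 to 705 ± 36.4 and MDM2 by 0.52 (adjusted p = 0.000481). Of 17 NF-kB cytokines and targets, 14 were higher and 0 lower, also 14 and 0 adjusted over the list alone, with a median of 1.08 (camera adjusted p = 0.000216, adjusted p = 0.472 with an estimated correlation). CXCL8 rose from 145 ± 10.5 to 2191 ± 217. Of 23 growth factor receptors and ligands, 14 were higher and 3 lower, 14 and 4 adjusted over the list alone, with a median of 0.43 (camera adjusted p = 0.0265, adjusted p = 0.472 with an estimated correlation). HGF rose from 73.2 ± 4.62 to 1011 ± 56.7 and EGFR by 0.66 (adjusted p = 2.28e-06). In this comparison the tested genes of chromosome 2, where MCM6 lies, had a median of 0.318. The medians were 0.308 on chromosome 4 (CXCL8), -0.312 on chromosome 6 (CDKN1A) and 0.255 on chromosome 7 (HGF and EGFR).

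Of 15 genes of homologous recombination and the Fanconi anemia pathway, 9 were higher and 0 lower, also 9 and 0 adjusted over the list alone, with a median of 0.25 (camera adjusted p = 0.0249, adjusted p = 0.633 with an estimated correlation). FANCA rose from 1088 ± 63.7 to 1690 ± 14.1. Of 21 nuclear genes of oxidative phosphorylation, 13 were higher and 0 lower, also 13 and 0 adjusted over the list alone, with a median of 0.20 (camera adjusted p = 0.0156, adjusted p = 0.856 with an estimated correlation). COX5A rose from 4763 ± 233 to 8554 ± 738. Of 13 mitochondrially encoded genes, 10 were lower and 1 higher, also 10 and 1 adjusted over the list alone, with a median of -0.33 (camera adjusted p = 0.0481, adjusted p = 0.895 with an estimated correlation). MT-ATP6 fell from 55820 ± 4451 to 39602 ± 2790. Of 18 glycolysis genes, 11 were higher and 1 lower, 12 and 1 adjusted over the list alone, with a median of 0.27 (camera adjusted p = 0.0265, adjusted p = 0.856 with an estimated correlation). The lactate transporter gene SLC16A3 rose from 7896 ± 740 to 14081 ± 159. Of 13 reference genes, 7 were higher and 2 lower, also 7 and 2 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.314). Its median of 0.21 was near those of homologous recombination, oxidative phosphorylation and glycolysis. Of 8 neuronal markers, 5 were higher and 1 lower, also 5 and 1 adjusted over the list alone, with a median of 1.08 (camera adjusted p = 0.0319, adjusted p = 0.472 with an estimated correlation). SNAP25, a synaptic vesicle fusion protein, rose from 41.8 ± 1.84 to 252 ± 19.

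Among single genes, ADARB2 rose from 0.805 ± 1.4 to 435 ± 20.4, the axon guidance receptor gene ROBO2 from 10.7 ± 1.66 to 547 ± 16.1, and the calcium channel subunit gene CACNG7 from 4.6 ± 1.11 to 444 ± 53.9. CPVL, MAGEB2, GABRG3-AS1, ICAM5, PRSS12, RPL39L and MAGEA6 were the rest of the 10 largest rises, and the antisense and MAGE values are uncertain. Beside RARRES2 and APOE, the 10 largest falls were KRT81, LIMCH1, LINC03061, the endothelial receptor gene TIE1 (698 ± 92.1 to 7.92 ± 2.41), TMEM132D-AS1, TUBA3C, PDZD2 and CES1. MSH6 rose by 0.77 (adjusted p = 9.06e-07), ITGA5 by 0.74 (2.15e-06) and MPG by 0.34 (0.000203), with a median of 0.32 over the genes of chromosome 2, where MSH6 lies. NES fell by 1.57 (adjusted p = 4.61e-06), and ABCG2 rose from 0.0735 ± 0.127 to 23.9 ± 3.12. PMS2 at 0.04 (adjusted p = 0.786) and SOX2 at -0.65 (0.0712, 0.00196 to 0.272 over the alternatives) did not pass, though SOX2 passed in 5 of 19 alternatives.

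In all, 4965 genes were higher and 4820 lower in R50_OFF than in R50, 59.5% of those tested, of which 1243 and 1510 changed at least 2-fold. Calls were lost with quantile normalization for glycolysis, whose median shrank to 0.12 (adjusted p = 0.428, 0.001 to 0.428 over the alternatives), and oxidative phosphorylation, whose median shrank to 0.03 (0.437, 0.000389 to 0.437), and without R50 replicate 3 for homologous recombination (0.0718, 0.000737 to 0.0718). Mitochondrially encoded genes lost theirs in 7 alternatives (0.0054 to 0.124), among them without parent replicate 2 (0.0619), R50 replicate 1 (0.0883) and R50_OFF replicates 2 and 3 (0.0774 and 0.124), and neuronal markers in 3 (0.0243 to 0.0656), among them without R50 replicate 1 (0.0574) and R50_OFF replicate 2 (0.0617). With no minimum value the median of neuronal markers shrank to 0.16 (adjusted p = 0.0309).

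The comparisons were set side by side to ask which changes of R50 were also present in R50_OFF and which had moved back. MSN, SLFN11, SYNDIG1, LMO2 and TBX2 were among the 10 largest falls, and CHL1 among the 10 largest rises, against parent in both lines. The difference between the lines was not past the test for MSN, SLFN11, SYNDIG1 or CHL1, while LMO2 (4.54 ± 1.29 in R50 and 25.3 ± 1.55 in R50_OFF) and TBX2 (20.5 ± 1.3 and 44.5 ± 7.87) were higher in R50_OFF. IL1B, HGF, TENM2, THY1 and EBI3 differed from parent in R50 and lay nearer to the parent level in R50_OFF, at 996 ± 188 for TENM2 and 488 ± 46.3 for THY1. Terms such as moved back, no longer called and moved further compare separate lines and do not follow 1 line over time. A gene that never changed in R50_OFF would also count as moved back.

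Of the 10422 genes called in R50 against parent, 5307 were called in the same direction in R50_OFF against parent, 2589 higher and 2718 lower, and 1082 in the opposite direction. Independent lists of these sizes would share 2712 in the same and 2713 in opposite directions. In 100 simulations all 3 groups, parent included, were drawn around a common mean per gene, which gave 0 of either. They called 0.08 genes on average in R50 against parent, so this 0 was set beforehand. It does not show what overlap to look for when both lines changed. Of the 10422, 6542 (62.8%) moved back, that is, they were called in the opposite direction in R50_OFF against R50. Independent lists would give 3099, but both comparisons hold the R50 libraries, with opposite signs. A gene out of line in R50 alone thus counts as moved back, so 3099 is no fair baseline. The simulations, which called hardly any gene, gave 0. Of these 6542, 3344 were no longer called against parent, 2116 were still called in the same direction and 1082 in the opposite one. Another 2339 were called in the same direction in both lines with no call between the lines, and 852 had moved further from parent in R50_OFF. Across 16456 genes, which are not independent replicates, the fold changes of the lines against parent had r = 0.632 and a covariance of 0.883, beside a simulated r of 0.497 and a simulated covariance of 0.0384. The simulated r came from sharing a parent group alone, so r = 0.632 is not by itself a sign of shared change. The simulated covariance holds noise only, without real changes. The comparisons share libraries, and 3 controls do not make 2 sets of at least 2 libraries, so they were not split. Part of the excess over independent lists may come from the shared controls, and for genes that moved back from the shared R50 libraries.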

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

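The tests of the trend on mean level, of chromosome copies, of a deletion next to MSN and of carried-over parental cells were chosen only after the results were seen, as were the threshold of 0.2 for a shifted chromosome, the limits of the carry-over test (4-fold, 5% and a level of 1000) and the choice of MSN. The tests of GC content and length, of MSN copies and of other splits were written down before their own values were seen, but after the changes of single genes were known, and the first of these uses the threshold of 0.2.

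Against parent, the median change in R50 was negative over the genes of chromosomes 2 (-0.34), 4 (-0.27) and 21 (-0.34) and positive on chromosomes 6 (0.32), 13 (0.21), 14 (0.30) and 19 (0.20), each with a permutation p = 0.0001 over random gene sets, the smallest they can give, and chromosome 7 at -0.198 just missed the threshold. The shifts of chromosomes 6 and 13 were regional, with windows of 10 Mb at 0.34 to 0.55 up to 60 Mb of chromosome 6 and 0.01 to 0.29 beyond, and at 1.24, 0.79 and 0.48 from 90 Mb of chromosome 13 and -0.20 to 0.25 before. The fall of chromosome 21 did not run through all of it either, since 3 of its 5 windows lay on the side of the shift. In R50_OFF against parent the medians were -0.05 on chromosome 2, -0.01 on 4, -0.04 on 6, 0.04 on 13, 0.19 on 14, 0.165 on 19 and 0.04 on 21, but the windows from 90 Mb of chromosome 13 stayed at 0.74, 0.60 and 0.61 (adjusted p = 0.00296 each). Chromosome 22, at 0.096 in R50 (adjusted p = 0.0772 over random gene sets), had the highest median in R50_OFF, 0.198 (0.0006). In R50, removing trends on GC content and transcript length kept at least 84.9% of each of the 7 shifts and removing the trend on mean level at least 79.6%, which argues against either trend as the whole cause there. In R50_OFF the first step took chromosome 19 from 0.165 to 0.07 (42.6% kept), chromosome 22 from 0.198 to 0.136, chromosome 13 from 0.04 to 0.135 and chromosome 14 from 0.192 to 0.189. The R50_OFF median of chromosome 19 may thus owe much to these trends. On chromosome 19, genes above the median level showed 23.7% of the shift of the weaker genes (95% bootstrap interval 12.4 to 36.4), which argues against extra copies of the whole chromosome as the only cause. The many risen zinc finger genes of chromosome 19 may add to the shift of its weaker genes. The share thus cannot exclude a change of copies beside them. For the other 6 chromosomes a gain or loss of copies in the clone and a regulatory change cannot be told apart. The lowest such share, 65.0% on chromosome 4, had an interval of 43.9 to 97.7. That of chromosome 13 ran from -2690 to 13500 and that of chromosome 21 from 43.3 to 380.3. The share was 109.3% (81.0 to 145.1) on chromosome 2, 108.5% (69.2 to 148.8) on 6 and 125.2% (74.9 to 218.2) on 14. Such shares go with a change of copies but do not exclude a regulatory one. A first test, in which 78 of 83 windows of these 6 chromosomes lay on the side of the shift, was set aside after chromosome 19, led by a gene cluster, also gave 6 of 6, and no DNA measurement was used here.

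MSN kept 0.693% of its parent reads in R50 and 0.789% in R50_OFF. Reads of its copies EZR, RDX and MSNP1 gained at most 1.03% of the reads that MSN lost, which argues against reads moved to copies. The nearest tested genes on either side, LAS1L at 53.6 kb (0.02 in R50 and 0.04 in R50_OFF) and EDA2R at 853.7 kb (0.74 and 0.01), had a lowest change of 0.009, which argues against a deletion that takes in either of them. A deletion of part or all of MSN that spares both neighbours, silencing of the gene and an effect of the drug stay open and were not tested.

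Of 1651 genes that changed at least 4-fold in R50, whether or not they moved back, 1201 had a level in R50_OFF between those of R50 and parent. Reading that level as a mix of parental and R50 cells gave a median of 65.9% parental cells over all 1651 (quartiles 24.1 and 92.0). The same reading of MSN gave 0.096%, and 12 of the 96 transcripts at or above 1000 in parent and at least 4-fold lower in R50 gave less than 5%, which argues against parental cells with normal MSN left in the released line. A remnant of parental cells that already lacked MSN, the withdrawal of the drug and a difference between clones stay open, since each group is 1 line.

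The 6 samples of a comparison make 10 splits, too few for a share under 0.05. The number of splits as large as the real one, itself included, was 1 in each comparison. With the 2 groups alone, the real split called 10192 genes in R50 against parent, 9082 in R50_OFF against parent and 9169 in R50_OFF against R50, and the highest other split called 0 in each. Each other split mixes the 2 groups, so their difference enters its spread. Such 0 calls were bound to follow from any large difference between the groups, whatever its cause.

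The effects of the resistant lines against parent differed by a test of R50_OFF against R50 in 9 lists. The median differences, R50_OFF minus R50, were 0.75 for S phase, 1.08 for NF-kB cytokines, 1.08 for neuronal markers, 0.43 for growth factors, 0.27 for glycolysis, 0.25 for homologous recombination, 0.20 for nuclear genes of oxidative phosphorylation, -0.33 for mitochondrially encoded genes and -0.52 for p53 targets. With an estimated correlation none of these lists passed.

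Of the genes named whatever their result and the 10 largest rises and falls of each line against parent, 31 of those reported here differed between the lines by the same test with limma. Over all tested genes, 59.5% were called in this comparison. The largest rises and falls were also picked from the same libraries, so the count says little about these genes in particular. R50_OFF was above R50 for ADARB2 by 8.18, MAGEB2 5.08, ABCG2 4.54, ACP3 4.50, PDZRN3 4.44, IL1B 4.23, HGF 3.77, FAR2 3.59, ITM2A 2.83, LMO2 2.27, TBX2 1.07, MSH6 0.77, ITGA5 0.74, EGFR 0.66, PAMR1 0.53 and MPG 0.34. The difference was negative for KRT81 (-8.68), EBI3 (-4.96), SLPI (-4.46), LINC01224 (-4.36), TENM2 (-3.60), ZNF91 (-3.23), ZNF681 (-3.10), THY1 (-2.87), CYRIA (-1.66), ZNF468 (-1.59), NES (-1.57), CDKN1A (-1.33), NCOR1P4 (-0.92), AQP9 (-0.80) and MDM2 (-0.52).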

How the results depend on the processing

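The voom fit and the fit on reads not divided by length were chosen after the data were seen. Of 300 values of the 15 counts under the alternatives, 295 stayed within 1.5 times the reported count. The other 5 came from the higher minimum value of 50, where fewer genes were tested: the genes at least 2-fold higher in R50 against parent were 1152 (reported 2062), those in R50_OFF against parent 714 higher (1238) and 521 lower (841), and those in R50_OFF against R50 786 higher (1243) and 784 lower (1510). Leaving out each library in turn gave 4411 to 5148 genes higher in R50 against parent (reported 5206) and 5632 to 6162 that moved back (6542). No scaling put the median of all genes beyond 0.024 in size, but the median differed by level. In R50 against parent, genes above the median level were at -0.074 and the weaker genes at 0.211. In R50_OFF against R50 they were at 0.064 and -0.139, and in R50_OFF against parent at -0.012 and 0.043. Small medians of lists of abundant genes may in part reflect this. Of 9581 values for 487 results of named genes, 9475 kept direction and side of the threshold, 93 lost the call, 13 gained one and 0 reversed. Of 2091 values for the 105 list results, 2020 were unchanged in this sense, 43 lost the call, 28 gained one and 0 reversed, and with an estimated correlation all 33 calls were lost. The cause was not tested. The planned count test was not run.

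The replicate number as a block gave 5335 higher and 5318 lower genes in R50 against parent, 4454 and 4357 in R50_OFF against parent, 5070 and 4976 in R50_OFF against R50, and 6742 that moved back. Deviations of the 9 pairs of samples with the same number correlated at -0.021 to 0.1, 0 of them above 0.1, and 2 samples correlated best with their own number. These values gave no clear sign of pairing by number. The block nevertheless called more genes than the reported fit in each comparison, so a pairing cannot be excluded with 3 samples per group.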

Other observations

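The choice of the zinc finger cluster was made only after its values were seen. A cluster of zinc finger genes on chromosome 19, which encode DNA-binding repressors, was mostly weak in parent and higher in R50. The 27 tested members between 20077994 and 24129968 had a median level of 1.3 in parent, 190.4 in R50 and 26.5 in R50_OFF, although ZNF431 (294), ZNF430 (284) and ZNF85 (186) were already well above that median in parent. All 27 were higher in R50 than in parent (median change 5.47), 23 were higher and 1 lower in R50_OFF than in parent (3.05), and 27 were lower in R50_OFF than in R50 (-2.66). Testing needed a value of at least 10 in at least 3 libraries. Members near 0 in parent could thus enter only through a resistant line, and members silent in every line were left out. The count of 27 and these medians are therefore partly set by the filter. Of 176 zinc finger genes elsewhere on the chromosome, 113 were higher and 14 lower in R50 (0.51), and of 219 on other chromosomes 89 were higher and 35 lower (0.13). In the span of the cluster the 9 long non-coding RNAs that passed the same filter had a median of 5.62 and 0 coding genes of other families were tested. Further along, up to 30 Mb, 6 such coding genes had a median of 0.09 and 5 long non-coding RNAs 0.66. Reads of such similar genes can be split between them, so single values are uncertain.

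Other lists fixed beforehand held single genes with large changes although the list did not pass. Of 17 apoptosis regulators, 10 were higher and 5 lower in R50, also 10 and 5 adjusted over the list alone (median 0.31, camera adjusted p = 0.279). BMF, which encodes a promoter of cell death, rose from 66.6 ± 10.2 (SD, n = 3) to 1559 ± 79.5 in R50 and was 227 ± 6.92 in R50_OFF. Of 14 stem-like glioma markers, 7 were higher and 4 lower in R50, also 7 and 4 adjusted over the list alone (median 0.34, camera adjusted p = 0.441). The adhesion gene L1CAM rose from 17.6 ± 4.99 to 2190 ± 328 in R50, and ALDH1A3, which encodes a retinaldehyde dehydrogenase, fell from 51968 ± 1093 to 2533 ± 161 and was 25718 ± 657 in R50_OFF. Of 20 mesenchymal glioma markers, 8 were higher and 9 lower in R50, also 8 and 9 adjusted over the list alone (median -0.18, camera adjusted p = 0.568), and CHI3L1, a secreted glycoprotein, was 5060 ± 76.8 in parent, 14817 ± 549 in R50 and 665 ± 36.1 in R50_OFF. Of 8 epithelial markers, 6 were higher and 1 lower in R50, also 6 and 1 adjusted over the list alone (median 2.43, camera adjusted p = 0.0534, 0.0137 to 0.132 over the alternatives), and the keratin gene KRT8 rose from 153 ± 9.13 to 860 ± 116. Of 22 interferon response genes, 7 were higher and 12 lower in R50, 7 and 13 adjusted over the list alone (median -0.56, camera adjusted p = 0.228).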
